A study of Mus musculus with 35 samples.

How the data were processed

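Whole-lung RNA of male C57BL/6 mice was measured on 35 Affymetrix HT MG-430 PM arrays, with 5 arrays in each of 7 dose groups (0, 1, 5, 10, 20, 40 and 120 ppm styrene). The titles of 1 array at 1 ppm and 1 at 5 ppm carry the same animal number, so whether each array came from its own animal is not known. Each animal inhaled styrene or clean air for 6 h, and tissue was taken on the morning after exposure. The deposited values are log2 probe set signals that the authors normalised; the processing notes name RMA and Partek without versions or settings. The values themselves run as RMA values on a log2 scale do, and the background step, the reference set of arrays and the order of steps are not given in the sources used here. Scan dates, array plates and exposure chambers are not given, so none was testable. No counts lie behind these values, and the number of arrays limits their precision.

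The table held 45141 probe sets, of which 104 were controls. The annotation used here listed 29449 probe sets with a gene, 28898 of them with exactly 1 gene symbol and 551 with several. The other 15588 non-control probe sets (34.61%) were not listed with a gene and were tested apart. For each of 17097 genes the probe set with the highest mean over all 35 arrays stood for the gene, and 7180 of these genes had over 1 probe set. Symbols in the gene lists were matched to the annotation by their current name, and members that it did not name were left out.

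A linear model with 1 mean per dose group was fitted to all 35 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 28 residual and 4.617 prior degrees of freedom). Input was read with data.table (1.17.8), and figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. Each dose was compared with 0 ppm, 120 ppm with 40 ppm, and each other dose with the next lower one. Further tests were the moderated F test over the 6 contrasts against 0 ppm and the slope on log2 of the dose plus 1 ppm. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg over the 17097 genes of each comparison, with a threshold of 0.05. "Rose", "fell" and "changed" are used for genes past this threshold, and standard errors (SE) are limma's.

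Before the data were examined, the comparisons, 18 pathway lists, 15 cell type marker lists and the rule for naming genes were fixed. The rule named, per comparison, up to 10 higher and 10 lower genes with the largest change past the threshold, leaving out provisional names, and up to 4 called members of each list. For the trend, the 10 smallest p-values in each direction took the place of the largest change. Cyp2f2, Cyp2e1 and Scgb1a1 were named in every comparison, and where no gene was called the 3 genes with the smallest p were named. Goblet cell, squamous repair and hepatocyte lists (3 lists) were written after the data were seen. For each list, members past the threshold were counted with the adjustment over all genes and with the adjustment over the list alone. Camera compared each list with all other genes with a preset inter-gene correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over 33 lists and 6 doses (198 tests). The 3 later lists were adjusted apart. Fry, which asks whether a list's genes move on balance 1 way and does not compare them with other genes, was run beside camera with the same adjustment.

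Summaries of each array (signal quartiles, spike-in and hybridisation controls, 3' minus 5' control differences and list means) were compared between groups of 5 by two-sided exact permutation tests, whose smallest possible p was 0.00794. Array groups were also searched for outlying arrays with Dixon's ratio.

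The calling steps were tested on simulated data for 17097 genes, with 50 genes at each of 4 fold changes and 25 at each of 2 dose slopes. At 5 arrays against 5, 10% of genes set to 1.25-fold, 72% to 1.5-fold, 94% to 2-fold and 100% to 4-fold were called. Of 16847 unchanged genes, 12 were called. A dose slope of 0.1 log2 per unit was called for 88% of genes and 0.3 for 100%. Camera called 0 of 32 random lists. Rates on real arrays may differ.

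Alternatives were fixed beforehand for every count: all non-control probe sets, leaving out dim genes, a fold change of at least 1.5, an adjusted p threshold of 0.1, trended and robust variance, array weights, arrays centred on their median, repeated quantile normalisation, fits of only the groups compared, a replicate block, leaving out each array in turn, and leaving out the 2 arrays whose titles both carry animal number 15 (1 ppm replicate 5 and 5 ppm replicate 1). The trend was also fitted on a linear dose scale, on dose ranks and without 120 ppm, and lists were also tested on the mean of a gene's probe sets. Added after the data were seen were a fit without the 120 ppm group, the poly-A spike-in level as a covariate, counts without the 120 ppm replicates 4 and 5, and counts among genes brighter than every nonspecific-hybridisation control. Folds and slopes of named genes were bounded, also after the data were seen, by setting each array (of the dimmer group for folds, every array for slopes) to at least its highest nonspecific-hybridisation control. Level trends were removed by a loess fit of each array's difference from the 0 ppm mean against that mean. That step, centring the arrays at 120 ppm and quantile normalising them again assume equal overall signal, which is not known here. The similarity of dose responses was set beside simulated unchanged groups and beside values with the 5 controls split into groups of 2 and 3.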

Results

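Gene expression was measured in whole lung of male C57BL/6 mice after a single 6 h inhalation of styrene, a volatile aromatic hydrocarbon that lung cytochromes oxidise. There were 35 arrays in 7 dose groups. The question was how the transcriptome changes with dose. Values are log2 signals of 17097 genes. Differences are against the 5 arrays at 0 ppm, with 5 arrays per dose, unless another group is named. Where arrays of the dimmer group lay below their highest nonspecific-hybridisation control, the fold is given as "at least", with those arrays set to that control, and log2 differences are as measured. Where the brighter group then lay no higher, its signal is called below that control, and no size is given except under alternative settings, where such genes are named. Cyp2f2, Scgb1a1, Inmt, Sftpd and Cxcl15, and Krt19 at 120 ppm, lie above log2 12, where the array may saturate, so the true sizes of their differences and slopes are uncertain. Xist, the transcript of the inactive X chromosome in females, stayed between 3.93 and 5.11 on the 35 arrays, and the Y-linked gene Kdm5d lay between 4.55 and 6.72.

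The arrays at 120 ppm stood apart from all others. The first principal component carried 60.7% of the variance. Its mean was 100.2 at 120 ppm (SD 19.3, n = 5) and lay between -20.5 and -4.89 at the other doses. Poly-A spike-ins, RNAs added before labelling, were 1.67 higher on the log2 scale (3.18-fold) at 120 ppm than at 0 ppm. The nonspecific-hybridisation controls were 0.401 higher, the hybridisation controls were 0.255 higher, and the upper quartile of signals fell by 0.44. Each had a two-sided exact permutation p of 0.00794, the smallest possible with 5 against 5 (Benjamini-Hochberg 0.0374). The lowest poly-A mean at 120 ppm was 7.73, and the highest among all other arrays was 6.89. At 20 ppm the poly-A difference was -0.26 (two-sided exact permutation p = 0.00794). The second component, with 9.51% of the variance, had a mean of -21.7 at 0 ppm, -23.6 at 1 ppm, -4.02 at 5 ppm, 17.4 at 10 ppm, 19.2 at 20 ppm, 12.2 at 40 ppm and 0.38 at 120 ppm.

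**Figure D1:**
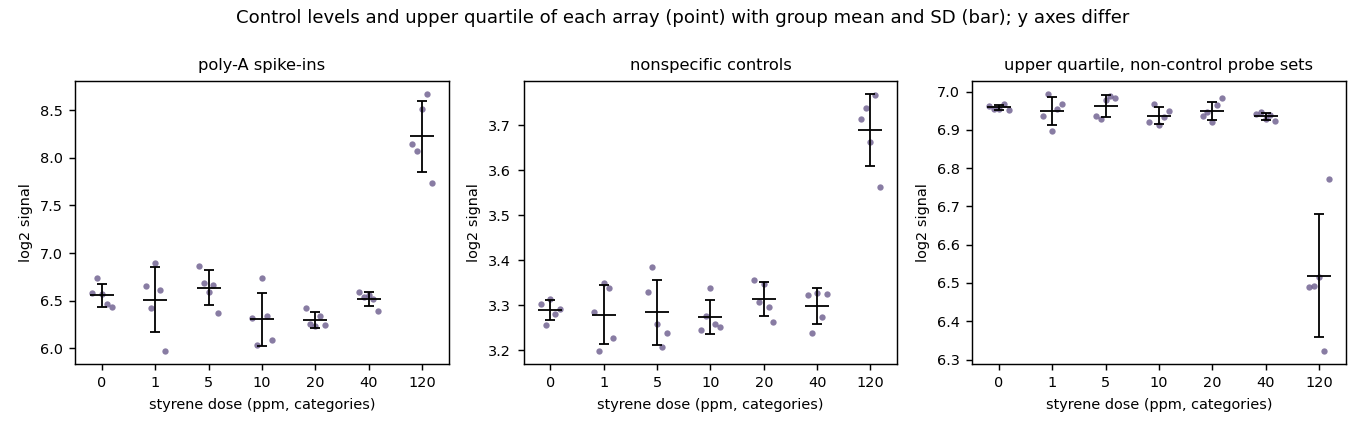
Log2 signal of the poly-A spike-ins, of the nonspecific controls and of the upper quartile on each of the 35 arrays, by styrene dose in ppm; points are arrays, and bars are the group mean and SD. Poly-A signal was at least 7.73 on the arrays at 120 ppm and at most 6.89 on the others.

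At 1 ppm no gene passed the threshold in limma (0 of 17097, smallest adjusted p = 0.105), and 1190 genes had an unadjusted p under 0.05. The 3 genes with the smallest p were Ces1g, Msln and Cd300c2, each with an adjusted p of 0.105 in limma. Ces1g, a carboxylesterase, was at least 1.87-fold higher (log2 1.38, SE 0.27), with all 5 arrays at 0 ppm below their highest nonspecific control, and was above every control on 4 of 5 arrays. Msln, the mesothelial protein mesothelin, was at 7.71 against 8.72 (SE of the difference 0.20), and Cd300c2, a myeloid surface receptor, differed by -0.67 (SE 0.13). For both, 5 of 5 arrays lay below every control. Adjusted over the list alone, 1 xenobiotic metabolism gene and 3 cardiac muscle markers rose, and 2 interferon response genes, 2 alveolar macrophage markers and 1 T cell marker fell. Camera with its preset correlation called 17 of 33 lists, 11 upward and 6 downward. With an estimated correlation it called 0, and fry called 1 (alveolar macrophage markers downward, adjusted p = 0.0122). Immediate early genes had a median of 0.24 (camera adjusted p = 0.216 with an estimated correlation) and cardiac muscle markers 0.78 (camera adjusted p = 0.261 with an estimated correlation). Alveolar macrophage markers had a median of -0.36 (camera adjusted p = 0.0685 with an estimated correlation, the smallest of the 33) and interferon response genes -0.25 (camera adjusted p = 0.438 with an estimated correlation). For genes changed at 1 ppm, limma gave 6 without 1 ppm replicate 2 and 43 with array weights, and with each array's level trend removed 2 rose and 1 fell. Of xenobiotic metabolism genes 1 rose without 1 ppm replicates 2 or 5.

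**Figure D2:**
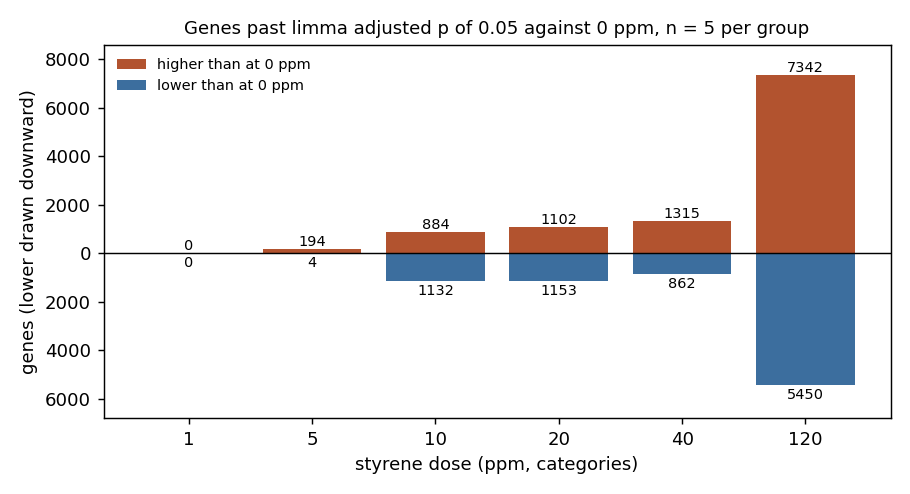
Number of genes past an adjusted p of 0.05 in limma at each styrene dose in ppm against 0 ppm; bars upward are genes higher, and bars downward are genes lower. Counts were 0 at 1 ppm, 194 higher and 4 lower at 5 ppm, and 7342 higher and 5450 lower at 120 ppm.

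At 5 ppm, genes of the interferon response, the antiviral programme of cells exposed to interferon, rose. The interferon-inducible gene Apol9a rose at least 5.22-fold (log2 3.57, SE 0.20), Oasl1 at least 4.55-fold (3.47, SE 0.23) and the viral RNA binding protein Ifit1 at least 9.92-fold (3.43, SE 0.31). The interferon transcription factor Irf7 rose at least 9.37-fold (3.36, SE 0.18) and the antiviral GTPase Mx1 at least 2.78-fold (3.18, SE 0.26). Cxcl10, an interferon-induced chemokine, rose at least 2.60-fold (3.13, SE 0.39). Agr2, a disulfide isomerase needed for mucin folding, rose at least 2.16-fold (2.88, SE 0.59). All 5 arrays lay beyond every control for these 7 genes (30 of 33 named genes). Of 13 interferon response genes 12 rose (12 adjusted over the list alone). In all, 194 genes rose and 4 fell in limma. Pon1, the antioxidant esterase paraoxonase, fell by 1.03 (SE 0.17). The lactate dehydrogenase subunit Ldhb (-0.41, SE 0.10) fell too. The other 2, cystathionine beta-synthase Cbs and the transcription factor Pax1, lay below the highest nonspecific control in both groups. Cbs no longer passed without 0 ppm replicate 3. Ldhb no longer passed without 0 ppm replicates 1 or 2 or 5 ppm replicates 4 or 5 (-0.39, -0.35, -0.38 and -0.39). Pax1 no longer passed without 0 ppm replicate 2 or 5 ppm replicate 4. With array weights, genes changed at 5 ppm numbered 321.

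Genes of DNA replication rose at 5 ppm in 13 of 28 cases (23 adjusted over the list alone). Uhrf1, which maintains DNA methylation, rose at least 1.56-fold (1.61, SE 0.17). Of 30 mitosis genes 4 rose (10 adjusted over the list alone), among them the kinases Pbk (at least 1.19-fold; 1.24, SE 0.19) and Cdk1 (at least 1.30-fold; 1.16, SE 0.22). Among genes brighter than every nonspecific control 9 DNA replication and 1 mitosis genes rose. Of 20 genes of the NRF2 and glutathione response, which protects against electrophiles, 5 rose (10 adjusted over the list alone). The glutathione peroxidase Gpx2 rose by 0.71 (SE 0.15) and the carbonyl reductase Cbr3 by 0.62 (SE 0.11). The NRF2 count was 3 without 0 ppm replicates 4 or 5 or 5 ppm replicate 2. Sterol synthesis genes rose in 3 of 14 cases (5 adjusted over the list alone), with Sqle, squalene epoxidase, 0.53 higher (SE 0.11). The sterol count was 1 without 0 ppm replicates 4 or 5 or 5 ppm replicates 1, 2 or 3. Camera with an estimated correlation kept 5 lists upward: interferon response (adjusted p = 8.75e-06), DNA replication (0.00195), sterol synthesis (0.0197), mitosis (0.020) and NRF2 (0.0347). Fry called 7 of 33 lists, 6 upward and 1 downward, these 5 among them.

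Of 19 cytokines and chemokines 3 rose at 5 ppm (4 adjusted over the list alone), and 1 did without 0 ppm replicate 2 or 5 ppm replicates 1 or 5. Camera's call was lost (adjusted p = 0.285 with an estimated correlation). For the unfolded protein and integrated stress response, 0 of 17 genes rose (3 adjusted over the list alone, camera adjusted p = 0.145 with an estimated correlation), and 1 did without 0 ppm replicate 3. Heat shock genes had a median of 0.19 with 0 of 11 called (0 adjusted over the list alone, camera adjusted p = 0.499 with an estimated correlation). Of 24 xenobiotic metabolism genes only Ces1g rose (at least 2.68-fold, 1.90, SE 0.27; 2 rose and 1 fell adjusted over the list alone). The median of that list was -0.12 and its mean 0.09. In limma, 0 genes passed in the immediate early (15), fatty acid synthesis (13), fatty acid oxidation (15), circadian (19), MHC class II (8) and collagen (19) lists. Adjusted over the list alone, 1 fatty acid oxidation gene and 1 collagen and matrix gene rose, and 0 changed in the other 4. Without 0 ppm replicate 1, 1 collagen and matrix gene rose in limma.

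At 10 ppm, 884 genes rose and 1132 fell in limma. With each array's level trend removed, 1142 rose and 909 fell. With array weights, genes changed at 10 ppm numbered 3586. Clca1, a secreted protein of mucous cells, rose at least 25.5-fold (log2 6.05, SE 0.83), Slc26a4, the anion exchanger pendrin, at least 6.47-fold (3.98, SE 0.37), and the acute phase protein Saa3 at least 9.44-fold (3.73, SE 0.42). Cxcl10 rose at least 7.67-fold (4.69, SE 0.39) and Mx1 at least 5.58-fold (4.18, SE 0.26). Genes that fell included Acaa1b, a peroxisomal thiolase (at least 3.23-fold; -2.60, SE 0.24), Pon1 (-2.38, SE 0.17) and the fatty acid binding protein Fabp1 (at least 3.21-fold; -2.06, SE 0.28). Asgr1, a subunit of the asialoglycoprotein receptor (at least 1.02-fold, -2.00, SE 0.23), and the xenobiotic-induced oxidase Cyp1a1 (at least 2.77-fold, -1.82, SE 0.36) also fell. All 5 arrays lay beyond every control for these 10 genes (81 of 98 named genes).

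All 13 interferon response genes rose at 10 ppm (13 adjusted over the list alone). DNA replication genes rose in 25 of 28 cases (26 adjusted over the list alone), with Uhrf1 at least 2.33-fold higher. Of 30 mitosis genes 16 rose (20 adjusted over the list alone). Among genes brighter than every nonspecific control, 3 mitosis genes, 16 DNA replication genes and 5 cytokines rose. Collagen and matrix genes rose in 13 of 19 cases (13 adjusted over the list alone). The metalloproteinase inhibitor Timp1 rose 10.8-fold (3.43, SE 0.26), tenascin Tnc at least 2.51-fold (2.79, SE 0.23) and Col1a1 by 0.97 (SE 0.15). Sterol synthesis genes rose in 10 of 14 cases (12 adjusted over the list alone), with Cyp51 2.28-fold higher. The unfolded protein and integrated stress response rose in 10 of 17 cases (12 adjusted over the list alone). Cytokines and chemokines rose in 8 of 19 cases (9 adjusted over the list alone), with the monocyte attractant Ccl2 at least 1.30-fold higher (2.30, SE 0.28). Xenobiotic metabolism genes of the lung fell in 15 of 24 cases and rose in 0 (17 and 2 adjusted over the list alone). Hepatocyte genes, a list written after the data were seen, had a median of -1.43 beside them (3 of 17 fell, camera adjusted p = 0.44 with an estimated correlation), and their list mean had an SD of 1.71 between the arrays at 0 ppm. The xenobiotic metabolism genes that fell included the aldehyde oxidase Aox3 (-1.33, SE 0.16), the carboxylesterase Ces1d (-0.99, SE 0.16) and the epoxide hydrolase Ephx1 (-0.82, SE 0.10). Camera kept these 8 lists with an estimated correlation. Adjusted p was 0.00126 for interferon response, 0.00261 for DNA replication, 0.00357 for collagen and 0.00424 for sterol synthesis. It was 0.020 for mitosis, unfolded protein response and xenobiotic metabolism (downward), and 0.0479 for cytokines. Fry called 16 of 33 lists, 10 upward and 6 downward, these 8 among them.

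NRF2 genes rose at 10 ppm in 7 of 20 cases (11 rose and 2 fell adjusted over the list alone), and camera's call was lost (adjusted p = 0.285 with an estimated correlation). Without 0 ppm replicate 5, 1 NRF2 gene fell. Gclc, which makes the glutathione precursor, was 0.78 higher (SE 0.17). Gsta2, a glutathione transferase, was 1.88 higher (SE 0.24), while its other probe set differed by -0.79. Of 11 heat shock genes 3 rose (7 adjusted over the list alone, camera adjusted p = 0.218 with an estimated correlation). That count was 0 without 10 ppm replicate 1, 1 without 0 ppm replicates 4 or 5 or 10 ppm replicate 2, and 5 without 0 ppm replicate 2 or 10 ppm replicate 5. Of 13 fatty acid synthesis genes 4 rose (5 adjusted over the list alone, camera adjusted p = 0.218 with an estimated correlation), and 2 did without 10 ppm replicate 1. Of 15 fatty acid oxidation genes 1 rose and 3 fell (1 and 4 adjusted over the list alone). Circadian genes, in tissue taken in the morning, rose in 1 and fell in 5 of 19 cases (1 and 5 adjusted over the list alone). Without 0 ppm replicate 4, 3 circadian genes fell. Immediate early genes rose in 4 and fell in 1 of 15 cases (5 and 1 adjusted over the list alone). Without 0 ppm replicates 1 or 2 or 10 ppm replicate 2, 2 rose, and without 10 ppm replicate 5, 1 rose. Of 8 MHC class II genes 1 rose and 1 fell (1 and 2 adjusted over the list alone), and 0 rose without 0 ppm replicates 2 or 4 or 10 ppm replicates 1, 3 or 5. The number that fell was 2 without 0 ppm replicate 2 or 10 ppm replicate 1, and 0 without any 1 of the other 8 arrays. The fatty acid oxidation gene that rose no longer passed without 0 ppm replicate 1.

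At 20 ppm, 1102 genes rose and 1153 fell in limma. With each array's level trend removed, 1289 rose and 1089 fell. For genes changed at 20 ppm, arrays centred on their median gave 1131 higher and 869 lower, and array weights gave 4061 in all. More genes also rose than fell without 0 ppm replicate 1 (995 and 872), 20 ppm replicate 2 (986 and 958) or 20 ppm replicate 3 (932 and 860). Cxcl10 rose at least 5.76-fold (log2 4.28, SE 0.39), Oasl1 at least 5.64-fold (3.78, SE 0.23) and Ifit1 at least 12.3-fold (3.74, SE 0.31). Prss22, a serine protease of the airways, rose at least 2.24-fold (3.25, SE 0.23) and the inflammatory cytokine Il6 at least 1.11-fold (2.71, SE 0.35). Genes that fell included Cyp1a1 (at least 2.91-fold, -2.56, SE 0.36), Pon1 (-2.12, SE 0.17) and the Myc family factor Mycl (at least 1.95-fold, -2.12, SE 0.23). The growth factor binding protein Igfbp3 (at least 3.40-fold, -1.78, SE 0.19) and the signalling adaptor Traf1 (at least 3.06-fold, -1.63, SE 0.24) also fell, as did Asgr1, below the highest nonspecific control in both groups. All 5 arrays lay beyond every control for these 11 genes (85 of 97 named genes).

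Interferon response genes rose at 20 ppm in 12 of 13 cases (13 adjusted over the list alone). DNA replication genes rose in 23 of 28 cases (25 adjusted over the list alone) and mitosis genes in 20 of 30 (25 adjusted over the list alone). Pbk rose at least 1.96-fold (1.96, SE 0.19), Cdk1 at least 2.19-fold (1.92, SE 0.22) and the ribonucleotide reductase subunit Rrm2 at least 1.10-fold (1.81, SE 0.16). Among genes brighter than every nonspecific control, 4 mitosis genes, 15 DNA replication genes and 5 cytokines rose. Sterol synthesis genes rose in 12 of 14 cases (13 adjusted over the list alone), with Cyp51 2.70-fold and Lss, lanosterol synthase, at least 1.83-fold higher. Collagen and matrix genes rose in 9 of 19 cases (11 adjusted over the list alone), and cytokines and chemokines in 9 of 19 (10 adjusted over the list alone). Xenobiotic metabolism genes fell in 12 of 24 cases (14 fell and 1 rose adjusted over the list alone), and Aox3 fell by 1.31 (SE 0.16). Without 0 ppm replicate 1, 1 xenobiotic metabolism gene rose. Camera kept these 7 lists with an estimated correlation. Adjusted p was 0.00195 for interferon response and sterol synthesis, 0.00357 for DNA replication and mitosis, 0.0243 for collagen, 0.0304 for cytokines and 0.0415 for xenobiotic metabolism. Fry called 17 of 33 lists, 9 upward and 8 downward, these 7 among them.

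NRF2 genes rose at 20 ppm in 9 of 20 cases (9 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.223 with an estimated correlation), and 1 fell without 0 ppm replicate 5 or 20 ppm replicate 1. The unfolded protein and integrated stress response rose in 7 of 17 cases (8 adjusted over the list alone, camera adjusted p = 0.216 with an estimated correlation). That count was 3 without 0 ppm replicate 1 or 20 ppm replicates 2 or 3, and 4 without 0 ppm replicates 4 or 5 or 20 ppm replicates 1 or 5. Immediate early genes rose in 5 and fell in 1 of 15 cases (6 and 2 adjusted over the list alone, camera adjusted p = 0.358 with an estimated correlation). The stress-induced transcription factors Atf3 (at least 2.91-fold; 1.86, SE 0.30) and Egr1 (1.29, SE 0.19) rose. MHC class II genes, which present antigen, fell in 4 of 8 cases (5 adjusted over the list alone, camera adjusted p = 0.546 with an estimated correlation). H2-Eb1 was at -0.59 (SE 0.11), and the count was 2 without 0 ppm replicate 5 or 20 ppm replicates 3 or 4. Heat shock genes changed in 0 of 11 cases (0 adjusted over the list alone; 1 rose without 0 ppm replicate 2), and fatty acid synthesis genes rose in 2 of 13 (2 adjusted over the list alone). Fatty acid oxidation genes rose in 2 and fell in 1 of 15 cases (2 and 2 adjusted over the list alone), and 0 fell without 0 ppm replicates 2, 3 or 5 or 20 ppm replicates 1, 3, 4 or 5. The number of immediate early genes that fell was 2 without 0 ppm replicates 4 or 5 or 20 ppm replicates 1 or 2. Circadian genes rose in 1 and fell in 3 of 19 cases (1 and 3 adjusted over the list alone).

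At 40 ppm, 1315 genes rose and 862 fell in limma. With every array centred on its median, genes changed at 40 ppm split into 1500 higher and 586 lower, and array weights gave 3883 in all. Prss22 rose at least 4.11-fold (log2 4.13, SE 0.23), Oasl1 at least 5.73-fold and Cxcl10 at least 4.04-fold (3.77, SE 0.39). Psapl1, a prosaposin-like protein, rose at least 2.38-fold (3.35, SE 0.23), Sectm1b, a protein of immune signalling, at least 1.92-fold (3.15, SE 0.25) and Timp1 6.74-fold (2.75, SE 0.26). Cyp1a1 fell at least 3.17-fold (-2.91, SE 0.36), Pon1 by 2.25 (SE 0.17) on the log2 scale, Asgr1 at least 1.06-fold (-1.97, SE 0.23) and Mycl at least 2.09-fold (-1.90, SE 0.23). Npr3, the clearance receptor for natriuretic peptides, fell at least 3.29-fold (-1.80, SE 0.40). All 5 arrays lay beyond every control for these 11 genes (82 of 101 named genes).

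Interferon response genes rose at 40 ppm in 12 of 13 cases (12 adjusted over the list alone). DNA replication genes rose in 20 of 28 cases (25 adjusted over the list alone), and mitosis genes in 18 of 30 (20 adjusted over the list alone). Among genes brighter than every nonspecific control 14 DNA replication and 4 mitosis genes rose. Sterol synthesis genes rose in 11 of 14 cases (12 adjusted over the list alone), with Cyp51 1.48 (SE 0.19) and Sqle 1.13 higher (SE 0.11), and Lss at least 2.22-fold higher (1.44, SE 0.20). Collagen and matrix genes rose in 10 of 19 cases (12 adjusted over the list alone). Camera kept these 5 lists with an estimated correlation. Adjusted p was 0.00195 for sterol synthesis, 0.00492 for interferon response, 0.0078 for DNA replication, 0.020 for mitosis and 0.0243 for collagen. Fry called 17 of 33 lists, 10 upward and 7 downward, these 5 among them.

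NRF2 genes rose at 40 ppm in 12 of 20 cases (13 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.163 with an estimated correlation), and 1 fell without 0 ppm replicate 5. The haem oxygenase Hmox1 was 0.91 higher (SE 0.17) and Gpx2 0.87 higher (SE 0.15). Immediate early genes rose in 9 of 15 cases (12 adjusted over the list alone, camera adjusted p = 0.0685 with an estimated correlation), among them Atf3 (at least 3.98-fold; 2.31, SE 0.30) and Egr1 (1.79, SE 0.19). Cytokines and chemokines rose in 9 of 19 cases (10 adjusted over the list alone, camera adjusted p = 0.0772 with an estimated correlation). Xenobiotic metabolism genes fell in 10 and rose in 2 of 24 cases (11 and 2 adjusted over the list alone, camera adjusted p = 0.0759 with an estimated correlation). The 2 that rose became 1 without 0 ppm replicates 1 or 4 or 40 ppm replicate 2, and 0 without 0 ppm replicate 5 or 40 ppm replicate 4. MHC class II genes fell in 4 of 8 cases (6 adjusted over the list alone, camera adjusted p = 0.381 with an estimated correlation), and in 2 without 40 ppm replicate 2. The unfolded protein and integrated stress response rose in 4 of 17 cases (4 adjusted over the list alone, camera adjusted p = 0.554 with an estimated correlation). Heat shock genes fell in 2 of 11 cases (1 rose and 2 fell adjusted over the list alone; 1 rose without 0 ppm replicates 1 or 2), and fatty acid synthesis genes rose in 2 of 13 (2 adjusted over the list alone). Fatty acid oxidation genes rose in 2 and fell in 1 of 15 cases (2 and 1 adjusted over the list alone). Circadian genes rose in 3 and fell in 1 of 19 cases (4 and 1 adjusted over the list alone), and 1 rose without 40 ppm replicates 1, 2 or 4. With 1 array left out, circadian genes fell in 0 to 2 cases (2 without 0 ppm replicate 1, 1 without 40 ppm replicate 5 and 0 without any other). Without 0 ppm replicates 2, 3 or 4 or 40 ppm replicates 4 or 5, 1 heat shock gene fell. Only without 0 ppm replicates 1 or 3 or 40 ppm replicate 2 did 2 fatty acid synthesis genes still rise, and 1 fatty acid oxidation gene rose without 0 ppm replicates 1 or 4 or 40 ppm replicates 2 or 5.

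**Figure D3:**
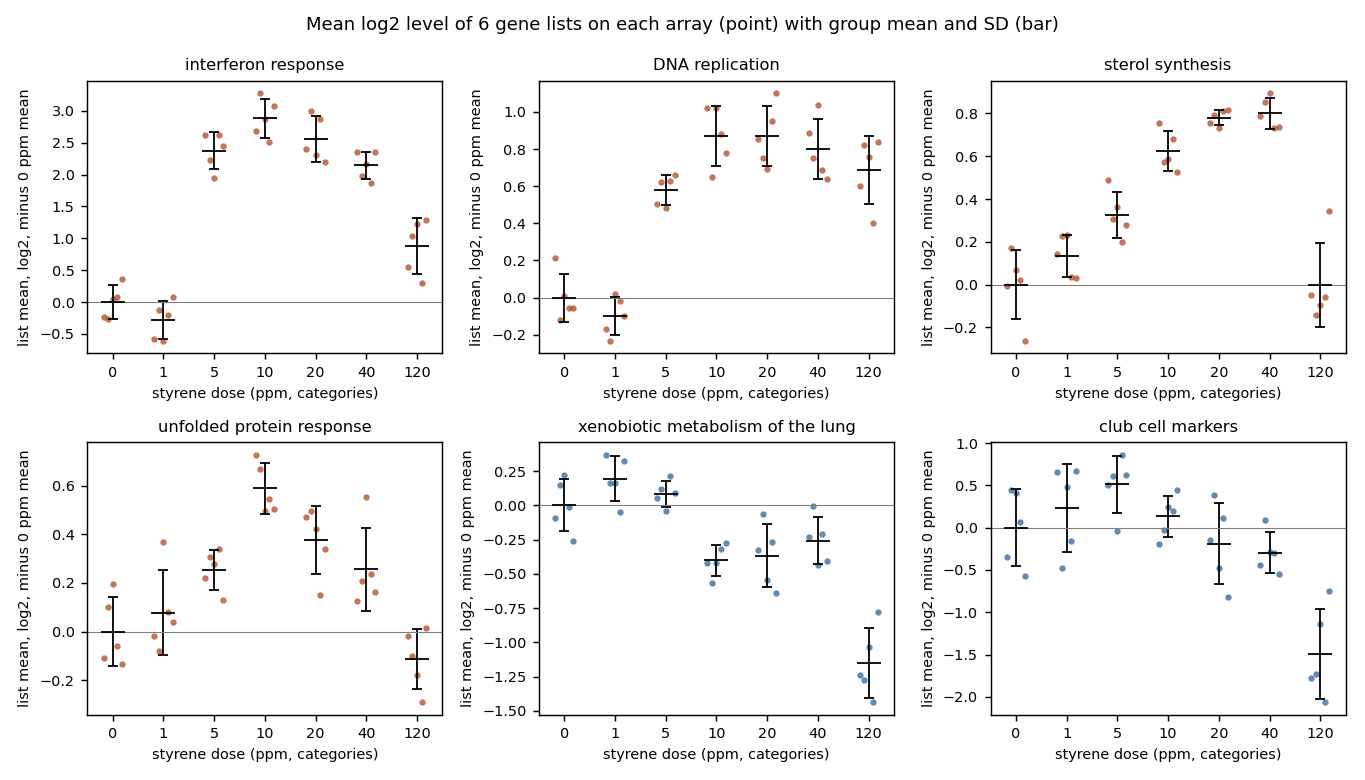
Mean log2 level of 6 gene lists on each array, minus the 0 ppm mean, by styrene dose in ppm; points are arrays, and bars are the group mean and SD. The interferon response mean lay at 2.38 at 5 ppm, 2.88 at 10 ppm, 2.14 at 40 ppm and 0.88 at 120 ppm.

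At 120 ppm, where the poly-A spike-ins were 3.18-fold higher, 7342 genes rose and 5450 fell in limma (74.8% of genes), around a median shift of 0.155. With each array's level trend removed, 5334 rose and 5512 fell. Prss22 rose at least 8.26-fold (log2 5.14, SE 0.23), Oasl1 at least 10.9-fold (4.73, SE 0.23), Psapl1 at least 6.14-fold (4.71, SE 0.23) and Irf7 at least 11.5-fold (3.65, SE 0.18). Tk1 rose at least 4.04-fold (3.37, SE 0.20) and Misp, a protein of spindle positioning, at least 5.94-fold (3.23, SE 0.17). Pon1 fell at least 11.4-fold (-3.58, SE 0.17), the protein glucosyltransferase Poglut1 at least 1.89-fold (-3.48, SE 0.20) and the cell cycle repressor Rbl2 at least 1.21-fold (-3.45, SE 0.25). Aox3 fell at least 6.28-fold (-3.39, SE 0.16) and Maob, monoamine oxidase, at least 4.36-fold (-3.15, SE 0.21). All 5 arrays lay beyond every control for these 11 genes (112 of 147 named genes). A fit with the poly-A level as a covariate called 4489 genes, and it shared 4081 with the 12792 genes changed at 120 ppm. Tested apart, genes brighter than every nonspecific control rose in 3015 and fell in 4117 cases.

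Many lists moved both ways at 120 ppm, with the poly-A spike-ins 1.67 higher on the same arrays. Camera called 5 of 33 with its preset correlation and 0 with an estimated one (smallest adjusted p = 0.223), while fry called 21, 8 upward and 13 downward. DNA replication genes rose in 19 and fell in 7 of 28 cases (19 and 7 adjusted over the list alone, camera adjusted p = 0.654 with an estimated correlation), with Uhrf1 at least 3.27-fold higher. Mitosis genes rose in 16 of 30 cases (16 adjusted over the list alone), with Cdc20 at least 2.60-fold higher. Among genes brighter than every nonspecific control, 3 mitosis genes, 10 DNA replication genes and 5 cytokines rose. Without 0 ppm replicates 2 or 3 or 120 ppm replicates 4 or 5, 1 mitosis gene fell. Immediate early genes rose in 11 of 15 cases (11 adjusted over the list alone, camera adjusted p = 0.429 with an estimated correlation), with Junb 2.51 higher (SE 0.18). Xenobiotic metabolism genes fell in 19 and rose in 2 of 24 cases (19 and 2 adjusted over the list alone, camera adjusted p = 0.223 with an estimated correlation). The aldehyde dehydrogenase Aldh1a7 was at -2.79 (SE 0.14). Interferon response genes rose in 7 and fell in 1 of 13 cases (7 and 1 adjusted over the list alone), with Ifit1 at least 3.69-fold higher (2.00, SE 0.31). Cytokines and chemokines rose in 11 and fell in 1 of 19 cases (11 and 0 adjusted over the list alone), and 0 fell without 0 ppm replicates 3, 4 or 5 or 120 ppm replicates 3 or 5. Collagen and matrix genes rose in 8 and fell in 5 of 19 cases (8 and 5 adjusted over the list alone). Sterol synthesis genes rose in 5 and fell in 7 of 14 cases (5 and 7 adjusted over the list alone), with the decarboxylase Mvd at least 3.65-fold higher (2.16, SE 0.17) and the desaturase Sc5d at least 2.11-fold lower (-1.87, SE 0.16).

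In the remaining pathway lists at 120 ppm, with upper quartiles differing by -0.44, NRF2 genes rose in 8 and fell in 7 of 20 cases. Unfolded protein and integrated stress response genes rose in 6 and fell in 9 of 17 cases. Fatty acid oxidation genes rose in 4 and fell in 8 of 15 cases. Fatty acid synthesis genes rose in 4 and fell in 6 of 13 cases, and 2 rose without 120 ppm replicates 2 or 5. Without 0 ppm replicate 5, 1 heat shock gene rose. Heat shock genes rose in 2 and fell in 6 of 11 cases, circadian genes rose in 6 and fell in 7 of 19, and MHC class II genes rose in 4 and fell in 1 of 8. Counts adjusted over the list alone were the same for these 7 lists.

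Between 40 and 120 ppm, 6798 genes were higher at 120 ppm and 5318 lower in limma. With each array's level trend removed, 5055 were higher and 5063 lower. The circadian output factor Dbp was at least 2.82-fold higher at 120 than at 40 ppm (log2 2.34, SE 0.57). Poglut1 fell at least 1.41-fold (-3.05, SE 0.20) and the membrane protein Tmem168 at least 2.10-fold (-2.73, SE 0.13). Interferon response genes fell in 11 and rose in 0 of 13 cases (11 and 1 adjusted over the list alone, camera adjusted p = 0.864 with an estimated correlation), with Oasl2 at least 4.25-fold lower (-2.15, SE 0.17). Sterol synthesis genes fell in 9 and rose in 3 of 14 cases (9 and 3 adjusted over the list alone), with Cyp51 at least 3.02-fold lower (-2.49, SE 0.19). MHC class II genes rose in 7 of 8 cases (7 adjusted over the list alone). Xenobiotic metabolism genes fell in 17 and rose in 4 of 24 cases (17 and 4 adjusted over the list alone, camera adjusted p = 0.864 with an estimated correlation). DNA replication genes rose in 9 and fell in 11 of 28 cases (9 and 11 adjusted over the list alone), with a median of 0.12 and a mean of -0.12. Fry called 22 of 33 lists, 5 upward and 17 downward, and camera 0 with an estimated correlation. A fit with the poly-A level as a covariate called 3238 genes, and it shared 2816 with the 12116 genes changed between 40 and 120 ppm.

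Neighbouring doses below 40 ppm differed in fewer genes. From 1 to 5 ppm 275 genes rose and 61 fell, from 5 to 10 ppm 257 rose and 537 fell, and from 10 to 20 ppm 11 rose and 8 fell in limma. Between 20 and 40 ppm 0 genes passed in limma (smallest adjusted p = 0.145), and 1995 had an unadjusted p under 0.05.

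Across the 7 doses, 13051 genes differed in limma's F test, and 6083 rose and 4788 fell with log2 dose. Tested apart, genes brighter than every nonspecific control rose with dose in 2693 and fell in 3610 cases. Slopes are per unit of log2 of the dose plus 1 ppm. The slope was 0.83 (SE 0.05) for Prss22, 0.67 (SE 0.03) for Psapl1 and 0.49 (SE 0.03) for Tk1. Tgm1, a cross-linking enzyme of squamous epithelium, had a slope of 0.48 (SE 0.03), and the epithelial keratin Krt19 a slope of 0.24 (SE 0.02). Falling genes included Pon1 (-0.50, SE 0.03), Aox3 (-0.44, SE 0.03), the bicarbonate transporter Slc4a5 (-0.44, SE 0.03), the club cell claudin Cldn10 (-0.33, SE 0.03) and Ldhb (-0.28, SE 0.02). Part of these slopes runs below the highest nonspecific control. Means lay below it at 0, 1, 5 and 10 ppm for Prss22, Psapl1 and Tgm1, and at 0 and 1 ppm for Tk1. They also lay below it at 120 ppm for Aox3, Slc4a5 and Cldn10. Set to that control on all 35 arrays, Cxcr2 had a slope of 0.109, so the control itself rose with dose. With each array set to at least that control, the slopes were 0.46 for Prss22, 0.34 for Psapl1, 0.26 for Tk1, 0.26 for Tgm1, -0.37 for Aox3, -0.19 for Slc4a5 and -0.28 for Cldn10. DNA replication genes rose with dose in 20 of 28 cases, mitosis genes in 19 of 30, immediate early genes in 10 of 15 and cytokines and chemokines in 12 of 19, and 0 fell in each. Xenobiotic metabolism genes rose in 1 and fell in 20 of 24 cases. Counts for these 5 lists were the same adjusted over the list alone. Among genes brighter than every nonspecific control, 3 mitosis genes, 10 DNA replication genes and 4 cytokines and chemokines rose with dose. Without the 120 ppm group, whose spike-in controls stood apart, genes with a dose trend numbered 4448, and genes differing among the 7 doses gave way to 5299 differing among 6.

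Cyp2f2, Cyp2e1 and Scgb1a1 were followed in every comparison. Cyp2f2, the styrene-oxidising cytochrome of club cells, had log2 differences from 0 ppm of 0.04 at 1 ppm and -0.13 at 5 ppm, neither past the threshold. It fell by 0.54 at 10 ppm, 0.66 at 20 ppm, 0.69 at 40 ppm and 0.80 at 120 ppm (SE 0.08 each, measured above log2 12). Cyp2e1, the other main styrene oxidase, passed at none of the doses up to 40 ppm. At 120 ppm it was at least 1.47-fold lower (-2.50, SE 0.80), which no longer passed with the poly-A covariate (-1.57). Scgb1a1, the secretoglobin of club cells, was at -0.15 at 40 ppm and -0.34 at 120 ppm (SE 0.05 each), both past the threshold and measured above log2 12. Its 40 ppm call was lost without any of 0 ppm replicates 2, 3, 4 or 5 or 40 ppm replicates 1, 3, 4 or 5 (values from -0.15 to -0.13), and with arrays centred (-0.10).

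**Figure D4:**
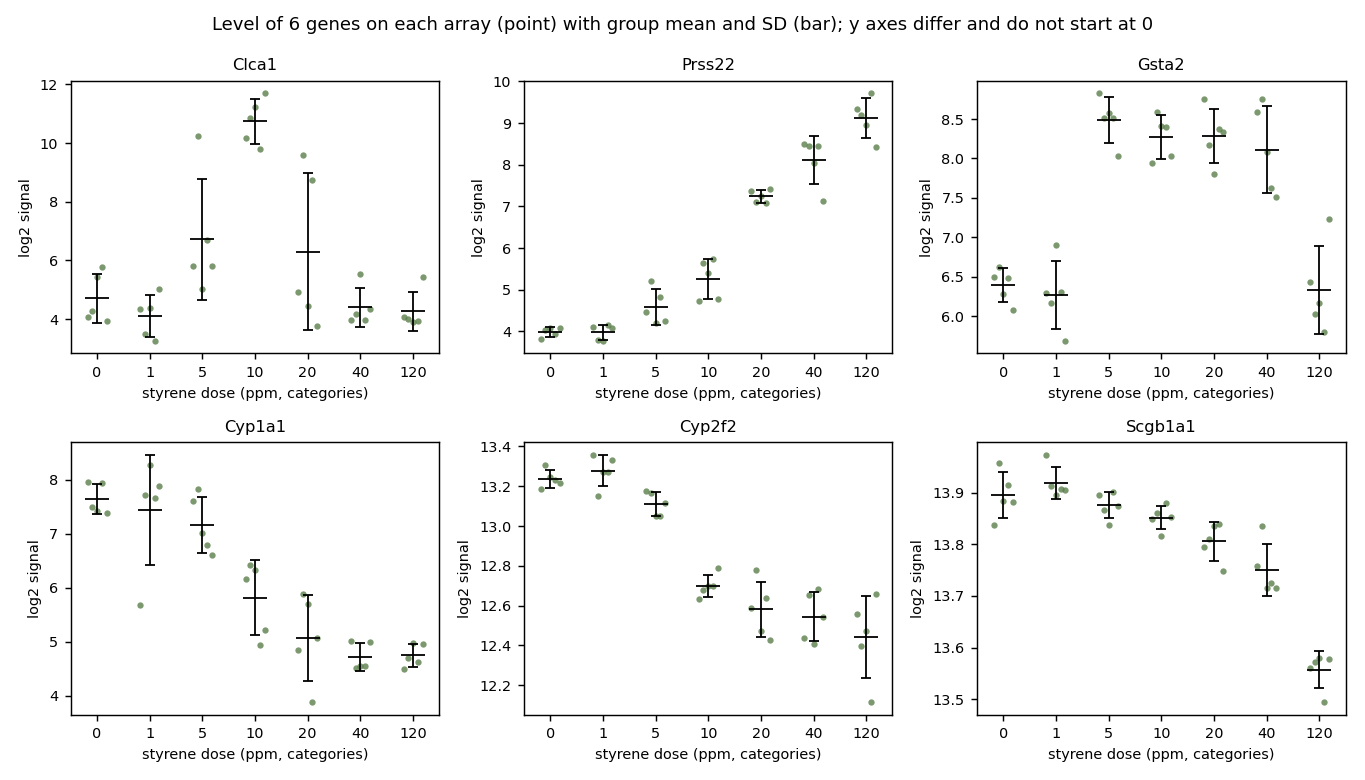
Log2 signal of 6 genes on each of the 35 arrays by styrene dose in ppm; points are arrays, bars are the group mean and SD, and the vertical axes differ and do not start at 0. Measured above log2 12, where the array may saturate, Cyp2f2 fell by 0.54 at 10 ppm and by 0.80 at 120 ppm, and Clca1 was at least 25.5-fold higher at 10 ppm.

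Club cell markers fell in 0 of 10 cases at 5 ppm (1 rose adjusted over the list alone), 4 at 10 ppm, 5 at 20 ppm, 7 at 40 ppm and 8 at 120 ppm (5, 6, 7 and 8 adjusted over the list alone, with 1 higher at 10, 20 and 40 ppm). Cldn10 was at -0.67 at 10 ppm (SE 0.15), -1.45 at 40 ppm and, with the poly-A spike-ins 1.67 higher, at least 3.13-fold lower (-2.17) at 120 ppm. At 10 ppm the count was 2 without 0 ppm replicates 2 or 3 or 10 ppm replicates 1 or 4. The median at 10 ppm was -0.22 and the mean 0.13. Cyp2a5 lay at 1.42 and the antimicrobial lectin Reg3g at 2.60 at that dose, neither past the threshold, and 1 club cell marker rose at 10 ppm without 0 ppm replicate 3. Cyp2a5, a cytochrome of the airways, passed at 40 ppm (2.21, SE 0.65) but not without 0 ppm replicates 1 or 5 or 40 ppm replicates 2 or 4 (1.96, 1.83, 2.03 and 2.04). Camera's calls for club cells were lost at 20, 40 and 120 ppm (adjusted p = 0.277, 0.0903 and 0.309 with an estimated correlation), and fry called them downward (adjusted p = 0.000433, 7.48e-06 and 1.44e-11) as at 10 ppm (0.0474). Alveolar macrophage markers fell in 0 of 8 cases at 5 ppm, 4 at 10 and 20 ppm, 3 at 40 ppm and 7 at 120 ppm (0, 4, 4, 5 and 7 adjusted over the list alone), with 1 higher at 10, 20 and 40 ppm. The marker higher at 10 ppm no longer passed without 0 ppm replicate 3 or 10 ppm replicate 5. Siglecf, a macrophage lectin, was at least 1.90-fold lower (-1.15, SE 0.14) and the lipid receptor Pparg at least 1.34-fold lower (-0.78, SE 0.14) at 10 ppm. Camera's calls for alveolar macrophages were lost at 5, 10, 40 and 120 ppm (adjusted p = 0.309, 0.389, 0.303 and 0.277 with an estimated correlation).

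Of 10 fibroblast markers 2, 2 and 3 fell at 10, 20 and 40 ppm (6, 4 and 4 adjusted over the list alone; camera adjusted p = 0.297, 0.309 and 0.303 with an estimated correlation). The methyltransferase Inmt was at -0.47 (SE 0.07) at 10 ppm. At 10 ppm 1 fibroblast marker fell without 0 ppm replicate 1, at 20 ppm 1 without 0 ppm replicates 1, 3 or 4 or 20 ppm replicates 3 or 5, and at 40 ppm 1 without 0 ppm replicates 1 or 5 or 40 ppm replicates 3 or 4. Endothelial markers fell in 3 of 10 cases at 20 ppm and 2 at 40 ppm (4 and 7 adjusted over the list alone), and 1 rose at 10 and 20 ppm. The growth factor receptor Kdr was at -0.51 (SE 0.12) and -0.59 (SE 0.12). Camera's endothelial calls at 5, 20 and 40 ppm were lost (adjusted p = 0.116, 0.377 and 0.258 with an estimated correlation). At 40 ppm 1 endothelial marker fell without 0 ppm replicates 4 or 5 or 40 ppm replicate 4. The endothelial marker that rose no longer passed at 10 ppm without 0 ppm replicates 3, 4 or 5 or 10 ppm replicates 1 to 4, and at 20 ppm without 0 ppm replicates 3, 4 or 5 or 20 ppm replicate 3. Among 9 alveolar type 2 markers 2 rose at 10 and 20 ppm, and 1 rose and 1 fell at 40 ppm (2 and 0, 2 and 1, and 1 and 1 adjusted over the list alone). The surfactant protein Sftpd was 0.32 higher (SE 0.07) at 10 ppm. At 10 ppm 1 type 2 marker rose without any 1 array but 0 ppm replicate 5, and at 20 ppm 1 rose without 0 ppm replicates 1 or 2 or 20 ppm replicates 2, 3 or 5. At 40 ppm 0 fell without 0 ppm replicates 4 or 5 or 40 ppm replicates 1 to 4. Among 9 alveolar type 1 markers 1 rose and 1 fell at 10 ppm, 1 rose at 20 ppm and 2 rose at 40 ppm (1 and 1, 1, and 3 adjusted over the list alone), with the water channel Aqp5 0.41 higher (SE 0.07) at 10 ppm. The type 1 marker that fell at 10 ppm no longer passed without any 1 of the 10 arrays, and 1 rose at 40 ppm without 0 ppm replicate 3 or 40 ppm replicates 1, 4 or 5. Ciliated cell markers fell in 1 of 11 cases at 10 ppm, 2 at 20 ppm and 0 at 40 ppm (1, 2 and 0 adjusted over the list alone), with Tppp3 at -0.47 (SE 0.10) at 10 ppm, and 1 fell at 20 ppm without 0 ppm replicate 2. With 1 array left out, 1 ciliated marker rose at 10 ppm (0 ppm replicate 2) and at 40 ppm (0 ppm replicate 2 or 40 ppm replicate 5), and 1 fell at 40 ppm (40 ppm replicate 4). At 5 ppm camera called them upward (median 0.25, adjusted p = 0.479 with an estimated correlation). In these 5 lists 0 markers passed at 5 ppm (0 adjusted over the list alone).

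At 120 ppm, with the poly-A spike-ins 3.18-fold higher, 3 endothelial markers rose and 6 fell of 10, and 1 fibroblast marker rose and 4 fell of 10 (0 and 4 adjusted over the list alone). The number of fibroblast markers that rose was 2 without 0 ppm replicate 1 or 120 ppm replicate 4, and 0 without 0 ppm replicates 2, 4 or 5 or 120 ppm replicates 1, 2 or 3. Ciliated cell markers rose in 3 and fell in 7 of 11 cases, type 2 markers rose in 1 and fell in 4 of 9, and type 1 markers rose in 4 and fell in 5 of 9. Apart from fibroblasts these counts were the same adjusted over the list alone. The endothelial adhesion protein Pecam1 was at -2.15 (SE 0.11).

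Markers of blood-borne cells passed in few cases below 120 ppm. Neutrophil markers fell in 1 of 10 cases at 10 ppm and 0 at 5, 20 and 40 ppm (2 adjusted over the list alone at 10 ppm). That gene, the granule protein S100a8 (-1.48, SE 0.46), no longer passed without 0 ppm replicates 1, 4 or 5 or 10 ppm replicates 1 or 2, and 3 fell without 0 ppm replicate 2. At 20 and 40 ppm 1 neutrophil marker fell without 0 ppm replicate 2. T cell markers fell in 0, 0, 1 and 2 of 10 cases at 5, 10, 20 and 40 ppm (the same adjusted over the list alone). The 1 at 20 ppm was lost without 0 ppm replicates 1, 3 or 5 or 20 ppm replicates 2, 3 or 4. The 2 at 40 ppm became 1 without 40 ppm replicate 1, and 0 without 0 ppm replicates 1, 3, 4 or 5 or 40 ppm replicates 2, 4 or 5. B cell markers changed in 0 of 8 and NK cell markers in 0 of 9 cases at these doses with every array. Without 0 ppm replicate 1, 1 B cell marker fell at 20 and 40 ppm. NK cell markers fell in 1 case at 10 and 20 ppm and 3 at 40 ppm without 0 ppm replicate 2. At 40 ppm 1 fell without 0 ppm replicate 4 and 2 without 40 ppm replicate 3. Adjusted over the list alone, 3 NK cell markers fell at 40 ppm (camera adjusted p = 0.309 with an estimated correlation) and 0 B cell markers changed. Red cell markers fell in 0, 1, 1 and 1 of 4 cases at 5, 10, 20 and 40 ppm (1 at each adjusted over the list alone), and camera's call at 5 ppm was lost (adjusted p = 0.277 with an estimated correlation). Alas2, which starts haem synthesis in red cells, was at -0.78 (SE 0.18) at 10 ppm. At 40 ppm 0 red cell markers fell without 0 ppm replicates 1, 2 or 3 or 40 ppm replicates 2, 4 or 5. Cardiac muscle markers changed in 0 of 8 cases from 5 to 40 ppm (0 adjusted over the list alone). Adipocyte markers rose in 1 of 7 cases at 40 ppm and thymocyte markers fell in 1 of 6 (the same adjusted over the list alone). These were the lipase Lipe (0.59, SE 0.17), which no longer passed without 0 ppm replicate 4, and the lipid-presenting protein Cd1d1 (-0.54, SE 0.15), which no longer passed without 0 ppm replicate 1 or 40 ppm replicate 4.

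At 120 ppm, on the arrays with nonspecific controls 0.401 higher, T cell markers rose in 5 and fell in 2 cases, B cell markers rose in 3 and fell in 1, and thymocyte markers rose in 3 and fell in 1. Red cell markers rose in 2 cases and adipocyte markers in 2. These counts were the same adjusted over the list alone. Neutrophil markers rose in 1 and fell in 1 case (1 and 0 adjusted over the list alone), and cardiac muscle markers fell in 1 (0 adjusted over the list alone). NK cell markers fell in 3 cases (1 adjusted over the list alone), and in 1 without 0 ppm replicates 3 or 5. Without single arrays, 3 neutrophil markers fell (0 ppm replicate 2 or 120 ppm replicate 5) or 2 did (0 ppm replicate 1), and 2 B cell markers fell (0 ppm replicate 1 or 120 ppm replicates 1 or 5). Red cell markers rose in 1 case without 120 ppm replicates 2 or 3, and adipocyte markers in 1 without 120 ppm replicate 2. Cardiac markers fell in 2 cases without 120 ppm replicate 3, and in 0 without 0 ppm replicates 2 or 3 or 120 ppm replicates 1 or 4.

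Of 8 AhR targets, genes induced through the dioxin receptor, the quinone reductase Nqo1 rose at 5, 20 and 40 ppm (at least 1.28-fold, 1.27-fold and 1.35-fold; 0.70, 0.68 and 0.77, SE 0.17) and Cyp1a1 fell at 10, 20 and 40 ppm. The 5 ppm call was lost without 0 ppm replicates 4 or 5 or 5 ppm replicates 1, 2 or 3. At 120 ppm, with the spike-ins higher, 2 AhR targets rose and 5 fell; 0 rose without 0 ppm replicate 4, and 1 without 0 ppm replicates 2 or 5 or 120 ppm replicates 2, 3 or 4. All AhR counts were the same adjusted over the list alone. Of 16 p53 targets 0 changed at 5 ppm, 2 rose and 1 fell at 10 ppm, 2 rose and 2 fell at 20 ppm, 3 rose at 40 ppm, and 6 rose and 7 fell at 120 ppm. Adjusted over the list alone these were 0, 3 and 1, 2 and 2, 3 and 1, and 6 and 7. At 20 ppm 1 p53 target rose without 0 ppm replicate 4, and 1 fell without 0 ppm replicates 1, 2, 3 or 5 or 20 ppm replicates 3 or 4. At 40 ppm 1 fell without 0 ppm replicate 1 or 40 ppm replicate 5. The apoptosis-linked nuclease Aen was 0.74 higher (SE 0.11) at 40 ppm. Of 14 glucocorticoid targets 1 rose at 5 ppm, 1 rose and 1 fell at 10 ppm, 2 rose at 20 ppm, 3 rose at 40 ppm, and 7 rose and 4 fell at 120 ppm. Adjusted over the list alone these were 1, 1 and 1, 2 and 2, 3, and 7 and 4, and at 40 ppm 1 rose without 40 ppm replicate 3. At 20 ppm 2 glucocorticoid targets fell without 0 ppm replicate 4 or 20 ppm replicate 2, and 1 without 0 ppm replicate 5 or 20 ppm replicate 1. The glucocorticoid target that fell at 10 ppm passed only without 0 ppm replicate 4 or 10 ppm replicate 2 and with all 10 arrays. The iron-binding protein Lcn2, also an acute phase gene, rose by 0.74 (SE 0.14) at 5 ppm and 1.95 at 20 ppm. Camera's glucocorticoid calls, downward at 5 ppm and upward at 40 ppm, were lost (adjusted p = 0.438 and 0.479 with an estimated correlation). It called neither the AhR nor the p53 list at any dose.

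Signs of the median, the mean and camera's direction also differed in lists that camera did not call. For p53 targets the median and mean were -0.02 and 0.0013 at 1 ppm, 0.01 and -0.0013 at 5 ppm, -0.08 and 0.0041 at 10 ppm and -0.09 and 0.03 at 40 ppm. For NRF2 genes at 120 ppm they were -0.04 and 0.08. The other cases lay in the circadian, AhR, fatty acid oxidation, type 2 and fibroblast lists at 1 ppm and the fibroblast and B cell lists at 5 ppm. Further cases were the glucocorticoid, ciliated and type 1 lists at 10 ppm, the ciliated, cardiac and adipocyte lists at 20 ppm, and the fatty acid oxidation, ciliated, type 2 and thymocyte lists at 40 ppm. Between 40 and 120 ppm they were the neutrophil and adipocyte lists.

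Differences at the doses were compared across genes, which are not independent replicates. The correlation across genes was 0.874 between 10 and 20 ppm, 0.834 between 20 and 40 ppm, 0.732 between 5 and 10 ppm and 0.498 between 40 and 120 ppm. All doses share the same 5 controls. Simulated unchanged groups gave a correlation of 0.501 and a covariance of 0.0116, against a covariance of 0.0973 for 10 and 20 ppm. With the controls split so that no array was shared, the correlations were 0.659, 0.415, 0.465 and 0.279. Of the 194 genes higher at 5 ppm, 180 were also higher at 10 ppm, against 10 for independent sets. At 10 and 20 ppm 702 genes were higher in both, against 57 for independent sets, and 737 were lower in both, against 76.3. At 10 and 120 ppm 477 genes were higher in both, against 380 for independent sets, and 517 lower, against 361, while 631 went opposite ways. The correlation was 0.177 there, and -0.0382 with the controls split.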

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

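Tests of RNA degradation, RNA input or labelling, immune cells, 1 or 2 animals and ciliated markers alone were chosen after the results were seen. Those of brightness-dependent compression, the ciliated minus club cell difference, fewer club cells and regrouped arrays were chosen before.

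The arrays at 120 ppm stood apart, and control features outside the gene comparisons differed there from 0 ppm. Poly-A spike-ins were 1.67 higher on the log2 scale, hybridisation controls 0.255 higher and nonspecific controls 0.401 higher. Brightness-dependent compression as the whole cause is argued against by 10846 genes called at 120 ppm with each array's level trend removed, against 2319 at 40 ppm. RNA degradation stays open: the 3' minus 5' difference of control genes changed by -0.0818, within its spread (SD 0.0852 at 0 ppm, two-sided exact permutation p = 0.246). A difference in RNA input or labelling cannot be told apart from the dose: no other array reached the poly-A level of this group, and with that level as a covariate 4489 genes were called at 120 ppm and 2703 at 40 ppm. A biological effect of the dose stays open beside it, untested.

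Most interferon response genes were higher from 5 to 40 ppm, and 11 of 13 were lower at 120 than at 40 ppm; Irf7 (0.37) and Ifit2 (-0.61) did not pass, and Oasl1, outside the list, lay at 8.60 at 40 ppm and 9.53 at 120 ppm. At 5 ppm 45 immune cell markers had a median change of -0.0862. Some (Camp, Cxcr2) lay at background throughout, so more immune cells stay open. The explanation of 1 or 2 animals is argued against by 5 of 5 arrays at 5 ppm with a list mean above every control array. With the level trend removed 10 of 11 genes were still called lower than at 40 ppm (median -1.08, before -1.44). The trend used 0 ppm levels (Mx1 4.37, at 40 ppm 7.44), so brightness-dependent compression stays open. An effect of the dose may underlie the rise, as a hypothesis found on the same data, and the fall at 120 ppm is confounded with the RNA input or labelling above.

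Of 10 club cell markers 4 fell at 10 ppm (2 without 0 ppm replicates 2 or 3 or 10 ppm replicates 1 or 4; list mean 0.132), 5 at 20 ppm, 7 at 40 ppm and 8 at 120 ppm, and camera called the list at none of these doses with an estimated correlation (adjusted p = 0.591, 0.277, 0.0903 and 0.309). Less airway tissue in the sample is argued against at 20 and 40 ppm, where ciliated cell markers had median changes of 0.0306 (SD 0.283) and -0.0186 (SD 0.274) against -0.53 and -0.629 for club cell markers, but the ciliated minus club cell difference of means, -3.60 at 0 ppm, was -3.48 at 20 ppm (two-sided exact permutation p = 0.492) and 0.321 higher at 40 ppm (two-sided exact permutation p = 0.0476), where arrays overlapped and the bound set beforehand, higher on every array, was not met. It cannot be told apart from a change within club cells at 10 ppm (medians 0.0399 and -0.221; difference of means -3.73, two-sided exact permutation p = 0.389) or 120 ppm (medians -0.691 and -1.14), where the spread of the ciliated markers (SD 0.293 and 1.00) exceeds the gap; at 120 ppm that difference, -2.61 (two-sided exact permutation p = 0.00794), lay above every control array on all 5 arrays, which goes against it, but on arrays whose controls stood apart. Fewer club cells, which would lower all 10 markers alike, stay open: at 40 ppm Cyp2a5, Reg3g and Scgb1a1 lay over 2 standard errors above the median, and Cldn10 (-1.45, SE 0.15), Cckar (-1.32, SE 0.25), Aldh1a7 (-1.18, SE 0.14) and Gabrp (-1.09, SE 0.22) below it, which goes against a uniform loss, but only 2 of the 3 above it lie under log2 12, fewer than the 3 set beforehand, and the median rests on Scgb3a2 and Cyp2f2, above log2 12, where the array may saturate. A biological effect of the dose on these cells may also contribute and was not tested apart.

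Arrays were regrouped at random in 100 splits per comparison, the real one included. For 8 of the 9 counts 1 split of 100, the real one, gave as many genes, which argues against chance alone. The real count and the highest other were 198 and 60 at 5 ppm, 2016 and 127 at 10 ppm, 2255 and 166 at 20 ppm, 2177 and 744 at 40 ppm, and 12792 and 10176 at 120 ppm. They were 12116 and 9897 between 40 and 120 ppm, 13051 and 4 in the F test, and 10871 and 7445 for the trend. At 1 ppm the real count was 0, which any split reaches (100 of 100), so the splits cannot decide. The highest other was 1880. That split set 0 ppm replicates 1 and 2 and 1 ppm replicates 1, 3 and 4, the 5 arrays with the highest poly-A levels, against the rest, which points to a structure among the arrays other than dose.

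Single arrays lay far from the other 4 of their group in 20 of 367 groups searched with Dixon's ratio, which by chance picks about 1 in 20 groups (18.4 here). Of these, 6 were on 120 ppm replicate 5. Its circadian list mean was 7.041 (nearest other array 6.767) and its sterol synthesis mean 7.672 (7.28). On the same array Poglut1 was at 6.08 (4.373), Rbl2 at 5.793 (3.64), Aox3 at 7.394 (6.556) and Alb at 4.619 (4.133). At 40 ppm replicate 3 had a mitosis mean of 5.291 (5.14) and an unfolded protein response mean of 9.705 (9.39). At 5 ppm replicate 3 had Irf7 at 8.876 (9.54) and Dhx58 at 7.748 (8.409). The AhR target mean was 6.808 (6.332) at 20 ppm replicate 2, and the p53 target mean 7.216 (7.097) at 10 ppm replicate 2. The heat shock mean was 9.522 (9.697) at 120 ppm replicate 3, and the fatty acid synthesis mean 9.032 (8.895) at 40 ppm replicate 4. The MHC class II mean was 9.34 (9.04) at 1 ppm replicate 3, and the red cell mean 7.727 (8.251) at 1 ppm replicate 5. The NK cell mean was 5.445 (5.138) at 5 ppm replicate 5, and the thymocyte mean 4.105 (4.193) at 5 ppm replicate 4. Scgb1a1 was at 13.97 (13.91) at 1 ppm replicate 1 and at 13.49 (13.56) at 120 ppm replicate 4.

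Of 15588 probe sets that the annotation lists with no gene, 9 passed the threshold in limma at 1 ppm and 36 at 5 ppm, all of them higher. There were 610 at 10 ppm (270 higher), 837 at 20 ppm (323 higher), 861 at 40 ppm (365 higher) and 9278 at 120 ppm (5338 higher).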

How the results depend on the processing

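The fit without the 120 ppm group, the poly-A covariate, leaving out 120 ppm replicates 4 and 5, which stand apart from the other 3, and the counts among genes above every nonspecific control were chosen after the results were seen.

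The results below are genes changed at 1 ppm, genes changed at 5 ppm, genes changed at 10 ppm, genes changed at 20 ppm, genes changed at 40 ppm, genes changed at 120 ppm, genes changed between 40 and 120 ppm, genes differing among the 7 doses (F test) and genes with a dose trend. Counts of genes stayed within 1.5 times with an adjusted p under 0.1, with dim genes left out, with trended and robust variance, with arrays centred, with quantile normalisation repeated, with only the groups compared, on dose ranks and on a linear dose scale, and without 120 ppm replicates 4 and 5. With a replicate block, whose numbers do not pair the arrays, they did too. With all probe sets, which tests more features, the counts were 3394 at 10 ppm, 4012 at 20 ppm, 3891 at 40 ppm, 30146 at 120 ppm, 27506 between 40 and 120 ppm, 30258 in the F test and 25696 for the trend. With a fold change of at least 1.5, which by construction leaves fewer genes, they were 799 at 10 ppm, 870 at 20 ppm, 838 at 40 ppm, 8174 at 120 ppm and 7583 between 40 and 120 ppm. Array weights gave 43 genes at 1 ppm, 321 at 5 ppm, 3586 at 10 ppm, 4061 at 20 ppm and 3883 at 40 ppm, and the cause was not tested. Without the 2 arrays numbered 15, 1 gene passed at 1 ppm. Without the 120 ppm group the trend gave 4448 genes, and the fit without that group gave 1 gene at 1 ppm and 5299 in the F test. With the poly-A covariate 4489 genes passed at 120 ppm, 3238 between 40 and 120 ppm, 6709 in the F test and 5135 for the trend. Among genes above every nonspecific control, which are fewer, 7132, 7040, 7562 and 6303 passed in the same 4 tests.

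With 1 array left out at a time, counts ran from 0 to 6 at 1 ppm (6 without 1 ppm replicate 2), 147 to 225 at 5 ppm, 1595 to 1968 at 10 ppm, 1792 to 2115 at 20 ppm and 1622 to 2117 at 40 ppm. They ran from 12234 to 12945 at 120 ppm, 11546 to 12394 between 40 and 120 ppm, 12456 to 13214 in the F test and 9541 to 11171 for the trend.

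List trend counts changed by over 1.5 times as follows, with causes untested unless given. Array weights gave 2 AhR targets (main 4), 8 unfolded protein response genes (13) and 5 fatty acid synthesis genes (8), and repeated quantile normalisation 2 AhR targets. A linear dose gave 12 sterol synthesis genes (7), 2 interferon response genes (10) and 5 MHC class II genes (3). Without the 120 ppm group the counts were p53 6 (12), unfolded protein response 6, heat shock 1 (8), glucocorticoid 4 (9), sterol 13, fatty acid synthesis 5, fatty acid oxidation 3 (11) and MHC class II 5. With the poly-A covariate they were AhR 2, p53 6, unfolded protein response 7, heat shock 3, glucocorticoid 5, sterol 12, fatty acid synthesis 5 and fatty acid oxidation 6. Members above every nonspecific control, by design fewer, gave mitosis 3 (19), DNA replication 10 (20), AhR 2 and cytokines 4 (12).

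With 1 array left out, list trend counts ran from 2 to 5 for AhR, 19 to 20 for DNA replication, 3 to 4 for MHC class II, 10 to 12 for NRF2, 8 to 11 for circadian, 11 to 12 for collagen, 10 to 13 for fatty acid oxidation, 7 to 9 for fatty acid synthesis and 8 to 11 for glucocorticoid. They ran from 7 to 9 for heat shock, 10 to 11 for immediate early, 12 to 14 for cytokines, 8 to 10 for interferon, 17 to 19 for mitosis, 11 to 12 for p53, 6 to 8 for sterol, 12 to 14 for unfolded protein response and 19 to 21 for xenobiotic metabolism.

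Of 21318 values of named genes under the alternatives, 20286 kept their direction and side of the threshold, 992 no longer passed, 8 newly passed and 32 reversed; for those 32 the cause was not tested. With quantile normalisation repeated the value was 0.02163 for Klrd1, 120 ppm. On a linear dose scale the slope was -0.0017 for Tnc, dose trend, and -0.002719 for Slc26a4, dose trend. Without the 120 ppm group the slope was 0.001902 for Tiparp, dose trend, 0.02312 for Dnajc3, dose trend, 0.001419 for Vnn1, dose trend, 0.02179 for Cxcl15, dose trend, -0.001033 for Camp, dose trend. For the lymphocyte markers it was -0.01635 for Thy1, dose trend, -0.01477 for Cd3e, dose trend, -0.01727 for Spib, dose trend, and -0.02992 for Cd79a, dose trend. With the poly-A covariate the value was 0.2096 for Rora, 120 ppm, -1.656 for Hspa1b, 120 ppm, 0.02455 for Klf9, 120 ppm, -0.2226 for Cdkn1a, 120 ppm, 0.2271 for Mmp8, 120 ppm, 1.869 for Ms4a1, 120 ppm, 0.2951 for Klrd1, 120 ppm, -0.4997 for Slc4a1, 120 ppm, and -0.4333 for Alas2, 120 ppm. Between doses with that covariate it was 0.8977 for Rora, 120 minus 40 ppm, 0.2897 for Klf9, 120 minus 40 ppm, 1.07 for Ptgs2, 120 minus 40 ppm, -0.07962 for Ccl17, 120 minus 40 ppm, -0.1623 for Foxj1, 120 minus 40 ppm. It was also 0.2023 for Cd3d, 120 minus 40 ppm, 2.397 for Ms4a1, 120 minus 40 ppm, -0.04333 for Lep, 120 minus 40 ppm, 0.09359 for Sytl2, 120 minus 40 ppm, and -0.5238 for Plaur, 120 minus 40 ppm. The slope was 0.001477 for Cxcl15, dose trend. Signals of Klrd1, Rora, Mmp8 and Ms4a1 at 120 ppm, of Rora, Ptgs2, Cd3d, Ms4a1, Lep and Sytl2 for 120 minus 40 ppm, and of Camp and Spib at every dose lay below the highest nonspecific control, and those of Cd3e and Cd79a did at 6 of 7 doses, so their signs rest on background.

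Signal over background is limited: 8077 of 17097 genes were brighter than every nonspecific control.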

Other observations

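The goblet cell, squamous repair and hepatocyte lists were written after the data were seen, and their results are given as values.

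Of 14 goblet cell and mucus genes 0 rose at 1 ppm, 1 at 5 ppm, 5 at 10 ppm, 2 at 20 ppm and 2 at 40 ppm (0, 1, 6, 2 and 3 adjusted over the list alone, with 1 lower at 10 ppm). Slc26a4 rose at least 6.47-fold (log2 3.98, SE 0.37) at 10 ppm, 3.76-fold (3.20) at 20 ppm and 1.71-fold (2.07) at 40 ppm. Camera's calls at 1, 5 and 10 ppm were lost (adjusted p = 0.44, 0.0999 and 0.0999 with an estimated correlation). At 120 ppm, where the poly-A spike-ins were 1.67 higher, 5 rose and 2 fell (4 and 2 adjusted over the list alone), with a median of 0.22 and a mean of -0.16. Fry called the list upward at 5 and 10 ppm (adjusted p = 0.0315 and 0.000474).

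Squamous and barrier repair genes rose in 0 of 16 cases at 1 and 5 ppm, 7 at 10 ppm, 8 at 20 ppm, 8 at 40 ppm and 13 at 120 ppm (0, 3, 7, 8, 8 and 13 adjusted over the list alone). Sprr1a, a precursor of the cornified envelope, rose at least 6.60-fold (log2 3.56, SE 0.25) at 10 ppm, and Tgm1 at least 1.84-fold (2.13, SE 0.15) at 20 ppm. Camera's adjusted p with an estimated correlation was 0.0148 at 10 ppm and 0.00929 at 20 and 40 ppm. Its calls at 5 and 120 ppm were lost (adjusted p = 0.182 and 0.157 with an estimated correlation). Fry called the list at 10, 20, 40 and 120 ppm and not at 5 ppm (adjusted p = 0.0838).

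Hepatocyte genes, 17 in the list, had medians of -1.22 at 5 ppm, -1.43 at 10 ppm, -0.84 at 20 ppm and -1.17 at 40 ppm. They changed in 0 cases at 1 and 5 ppm, fell in 3 at 10 ppm, 1 at 20 ppm and 1 at 40 ppm, and rose in 2 and fell in 3 at 120 ppm (0, 0, 3, 1, 1, and 2 and 2 adjusted over the list alone). Camera's calls at 5, 10 and 40 ppm were lost (adjusted p = 0.191, 0.44 and 0.44 with an estimated correlation), and fry called the list at no dose (smallest adjusted p = 0.0838). The SD of the list mean between arrays was 1.71 at 0 ppm, 1.82 at 1 ppm, 0.339 at 5 ppm, 0.133 at 10 ppm, 1.38 at 20 ppm, 0.128 at 40 ppm and 0.0763 at 120 ppm.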
